A study of Mus musculus with 8 samples.

How the data were processed

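Total RNA of mouse small intestine (Mus musculus, wild-type genotype) was measured by bulk RNA sequencing in 8 samples. The mice had been kept at 7% oxygen for 7 days; 4 samples came from mice without further treatment (Hypoxia) and 4 from mice that also received 4 mM nitrate (Hypoxia+Nitrate). Group and replicate number were taken from the sample titles. The labels do not say that each sample came from a separate animal, so p-values measure the spread between these samples.

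Per the labels' protocols, tissue was kept in a stabilising solution, RNA was isolated with TRIzol, and libraries were made with a strand-specific kit. The protocol text speaks of islets at the RNA isolation step although the tissue is given as small intestine. Per the submitters' processing notes, the tools were HISAT, featureCounts version 1.5.0-p3 and DESeq version 1.8.3, with genome build GRCm38. The aligner's version, the annotation, the strand setting and the treatment of duplicate and multi-mapping reads are not given in the sources used here. The authors deposited whole-number read counts per gene, as a table of all samples and as a table per sample; the 8 per-sample columns were identical to the columns of the joint table. The files held 55421 genes, of which 55154 IDs matched GENCODE M21 on the same build; 267 did not. Among the deposited gene names 27 had been turned into dates, so IDs were used throughout.

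The deposited counts look as if they were made without regard to strand and with ambiguous reads dropped. Of 217 genes covered along their whole exonic length only by exons of the opposite strand, between 89.4% and 94.9% had a count of 0 in each library, against 3.48% to 6.52% of 35883 genes without any overlap in the Hypoxia libraries. In the Hypoxia+Nitrate libraries 26.6% to 51.7% of the genes without overlap had a count of 0. The ribosomal DNA gene AY036118 went against this rule. It has 0 bp of exonic sequence free of other genes, yet held 7, 8692397, 130753 and 2010049 counts in Hypoxia 1 to 4. The overlapping gene CT010467.1 held 14735746, 6698045, 89610 and 1744494. The cause was not tested. Values of overlapping and antisense genes are therefore uncertain.

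Differential expression was tested in R version 4.3.3 with edgeR version 4.0.16: filterByExpr (minimum count 10, minimum total 15), TMM scaling, and the quasi-likelihood test of Hypoxia+Nitrate against Hypoxia with Benjamini-Hochberg adjustment at 0.05. CPM values were computed by edgeR from the deposited counts with TMM scaling. Standard errors of log2 fold changes were derived from the fitted fold change and its F statistic. A fixed set of 47 gene lists was tested with camera of limma version 3.58.1 at a preset inter-gene correlation of 0.01, on lists with at least 5 measured members. Lists, tests, most alternatives and the rule for named genes were set before the data were examined. The lists covered hypoxia, nitrate, stress and metabolic pathways, epithelial cell types and functions, immune and other cell types, tissues that contaminate gut samples, time of day and handling. Named genes were the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and groups that did not overlap, leaving out predicted models, immunoglobulin and T cell receptor segments and pseudogenes; up to 3 members of each list with the lowest p; of which part is printed, chosen after their values were seen; and Slc17a5, Hif1a, Epas1, Vegfa, Tjp1, Ocln, Cldn1, Muc2, Lgr5 and Mki67. Where a gene had no count in a whole group, its fold is a bound against a floor of 3 counts per library.

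A background level per library was estimated from 1469 autosomal odorant, vomeronasal and trace-amine receptor genes, as counts per kb of exonic sequence that no other gene overlaps. These genes were assumed to be mostly silent in gut tissue, which was not tested. The expected background of a gene was that density multiplied by its own unique exonic length, with a factor of 0.5 on X and Y. This estimate, and the alternatives built on it, were chosen after seeing the data. The alternatives chosen beforehand were other scalings (RLE, upper quartile, library size), no filter, a filter of CPM 1 in 4 samples, DESeq2 version 1.42.0, limma-voom with and without quality weights, the replicate number as a block, leaving out each sample, leaving out immunoglobulin, hemoglobin, pancreas and mitochondrial genes, an estimated inter-gene correlation, and fry. Alternatives added later were nuclear protein-coding genes alone, the background share as a covariate, subtraction of the expected background followed by limma-voom, and fits without Hypoxia+Nitrate 1 and 4 or without Hypoxia 1 and 2.

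The scripts were tested on simulated data with 200 changed genes drawn from the real means, dispersions and library sizes of this comparison. The TMM factors were not simulated, and the simulation without background also raised the ribosomal protein list. Of 35431 simulated genes, 27019 passed the filter. The edgeR test called 68.8% of the 96 genes changed by 4 on the log2 scale and 3.09% of the 97 changed by 2, with 3 false calls among 26796 unchanged genes. With even background added at the measured densities to 20102 protein-coding genes, edgeR made 58 false calls among 19911 unchanged genes, camera called 12 unchanged lists (0 after subtraction, 3 with the covariate), and edgeR estimated a median size of 2.08 for genes changed by 4. Subtraction returned a median of 4.26 for those genes and called 47.0% of 66, with 1 false call. The covariate fit called 0 of 75 such genes and gave 92.0% of them the right sign. The simulated background was drawn evenly around the same level that was then subtracted. The measured background varied far more between receptor genes, with variance over mean of 27.2 to 48.6 in Hypoxia and 120 to 399 in Hypoxia+Nitrate. The low number of false calls after subtraction therefore says little about the real calls. After subtraction the share of background-free counts held by the brush border and ribosomal protein lists was also compared between groups, a test chosen after seeing the data.

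Total counts ran from 5345377 to 63943036 per sample. No group at normal oxygen was analysed here.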

Results

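Small intestine of mice kept at low oxygen was compared with and without nitrate supplementation by RNA sequencing, with 4 samples per group. The question was which intestinal genes differ when nitrate, a dietary anion that the body can reduce to nitric oxide, is given during hypoxia. Total counts were 19879554, 21835865, 5345377 and 9119048 in Hypoxia 1 to 4 and 63943036, 10704437, 8662279 and 52189300 in Hypoxia+Nitrate 1 to 4.

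The groups differed in what their libraries held. Counts were present for 90.9% ± 1.75 (SD, n = 4) of annotated genes in Hypoxia and 57.1% ± 9.21 (SD, n = 4) in Hypoxia+Nitrate (exact permutation test, 2-sided p = 0.0286, the smallest that 4 against 4 samples can give). Odorant, vomeronasal and trace-amine receptor genes, assumed here to be mostly silent in gut tissue, had counts in 99.0% to 99.6% of cases in each Hypoxia library, and in 31.2%, 82.4%, 55.5% and 41.1% of cases in Hypoxia+Nitrate 1 to 4. The background expected from these receptor genes amounted to 51.0% ± 10.6 (SD, n = 4) of nuclear protein-coding counts in Hypoxia and 12.1% ± 10.9 (SD, n = 4) in Hypoxia+Nitrate (exact permutation test, 2-sided p = 0.0286). Protein-coding genes of the mitochondrial genome took 0.768% ± 0.279 (SD, n = 4) of counts in Hypoxia, against 64.0%, 7.31%, 6.90% and 49.3% in Hypoxia+Nitrate 1 to 4. A ribosomal DNA locus on chromosome 17 (Gm26917, Gm42418, AY036118 and CT010467.1; GRCm38, 39843013 to 39848827) took 75.7%, 73.7%, 7.06% and 45.0% of counts in Hypoxia 1 to 4 and 2.33%, 22.0%, 4.95% and 3.42% in Hypoxia+Nitrate 1 to 4.

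**Figure D1:**
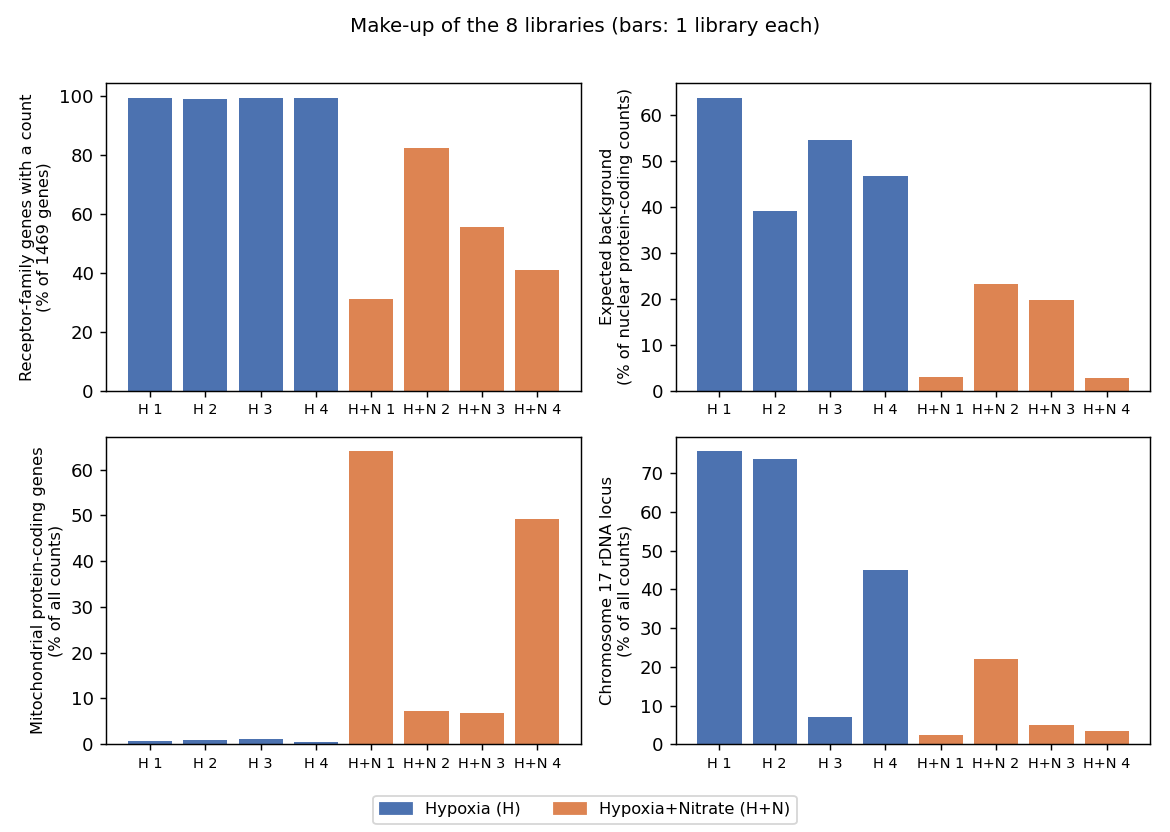
Each bar is 1 library, Hypoxia in blue and Hypoxia+Nitrate in orange; the panels give receptor-family genes with a count, the expected background, mitochondrial protein-coding counts and counts at the chromosome 17 rDNA locus, each in percent. The 4 Hypoxia libraries reach 39.1% to 63.7% expected background, above the 2.75% to 23.2% of the Hypoxia+Nitrate libraries.

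In Hypoxia+Nitrate, genes of the absorptive epithelium, of ribosomes and of mitochondria were higher than in Hypoxia, while many genes with no count in Hypoxia+Nitrate, receptor and protocadherin genes among them, were lower. Fabp2, the intestinal fatty acid binding protein (ENSMUSG00000023057, chromosome 3, 122895072 to 122899506), rose from 57.5 ± 72.7 to 6948 ± 8068 CPM (mean ± SD, n = 4 per group), a log2 fold change of 6.92 (SE 2.09, edgeR quasi-likelihood adjusted p = 0.0350). Rbp2, which carries retinol in enterocytes (chromosome 9, 98486115 to 98509781), rose by 6.70 (SE 1.73, adjusted p = 0.0199), and Anpep, a brush border peptidase (chromosome 7, 79821803 to 79861059), by 6.41 (SE 1.5, adjusted p = 0.0142), in each case with every Hypoxia+Nitrate value above every Hypoxia value. Of 35431 genes tested, 8653 passed an adjusted p of 0.05, 4163 higher and 4490 lower in Hypoxia+Nitrate, and each of the 8653 differed by a factor of at least 2. The count fell to 1932 without Hypoxia 1, 4235 without Hypoxia 3, 4434 without Hypoxia 4 and 5690 without Hypoxia 2, and reached 22454 without Hypoxia+Nitrate 2 and 14697 without Hypoxia+Nitrate 3. It was 4227 without Hypoxia 1 and 2, and 11637 without Hypoxia+Nitrate 1 and 4.

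Scaling set much of the balance between the directions. The median log2 fold change of all genes was −0.58 with TMM, −0.87 with RLE, −0.94 with upper-quartile factors and −1.07 with library size alone. Higher genes made up 48.1% of the calls with TMM, 35.0% of 9249 with RLE, 34.4% of 8269 with upper-quartile factors and 13.5% of 1800 with library size alone. Once the expected background was subtracted, 2000 of 14974 protein-coding genes passed in limma-voom, 634 higher and 1366 lower, and 1227 of the 8653 were called in the same direction. With the background share as a covariate 292 genes passed.

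The other genes among the 10 largest rises were mitochondrially encoded or epithelial, apart from a pair with overlap. mt-Atp8, mt-Nd4l and mt-Nd3, subunits of the respiratory chain and ATP synthase, had log2 fold changes of 8.10, 7.03 and 6.77 (adjusted p = 0.0435, 0.0282 and 0.0201, edgeR). Ezr, the brush border linker ezrin, and its partner Slc9a3r1 rose by 6.61 and 6.46 (adjusted p = 0.0145 and 0.0223, edgeR). Mrpl53, a mitochondrial ribosome subunit, and Trex1, a DNA exonuclease, had no count in any Hypoxia library and were at least 35.9-fold and 28.0-fold higher in Hypoxia+Nitrate; only 12% of the exonic length of Mrpl53 and 0% of that of Trex1 is free of other genes, so their counts are uncertain.

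The 10 largest falls had no count in any Hypoxia+Nitrate library, and their folds are bounds against 3 counts per library. They were Kcns2, a potassium channel subunit (chromosome 15, 34837355 to 34843407, at least 47.9-fold lower), Efnb3 (43.7), Krt77 (39.4), Olfr147 (38.5), Pcdhb17 (36.6), Pcdhb8 (35.6), Klhl14 (35.1), Olfr1 (34.6), the antisense RNA BB031773 (33.5) and Sh2d1b1 (32.6). Efnb3 and the Pcdhb genes are known from neurons, Krt77 from skin and the Olfr genes from the nose. In Hypoxia these genes held 5.65 to 8.31 CPM, and their counts lay between 1.17 times (Olfr147) and 2.50 times (BB031773) the expected background. Of 1307 receptor-family genes tested, 342 were lower and 6 higher. Long non-coding and unverified (TEC) loci were lower for 1645 of 8708 and higher for 100, and pseudogenes lower for 859 of 5997 and higher for 309. Of the 4490 lower genes, 1273 had no count in any Hypoxia+Nitrate library. Groups did not overlap for 40.8% of the genes tested, where chance gives 2.86%.

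Genes of absorptive enterocytes rose together. Of 25 brush border genes 21 rose, 0 fell and 4 did not pass (22 adjusted over the list alone), with a median log2 fold change of 4.66 (camera adjusted p = 2.95e-09, or adjusted p = 0.36 with an estimated correlation). Slc6a19, a neutral amino acid transporter, rose by 4.80 (SE 1.09). Hypoxia counts of the brush border and lipid absorption lists lay at a median of 1.74 and 2.19 times the expected background. Of 21 genes of dietary lipid absorption 19 rose and 0 fell (20 adjusted over the list alone, median 4.01, adjusted p = 7.94e-10, or adjusted p = 0.36 with an estimated correlation), including Sar1b, needed to export chylomicrons, by 5.37 (SE 1.02), and Mogat2, a monoacylglycerol acyltransferase, by 4.94 (SE 1.03). PPAR-alpha and fatty acid oxidation genes rose for 17 of 25 and fell for 1 (20 and 2 adjusted over the list alone, median 2.87, adjusted p = 2.54e-07, or adjusted p = 0.36 with an estimated correlation), with Acaa2, a thiolase, at 4.34. Markers of the duodenum and jejunum (7 of 12 rose, 1 fell; 8 and 2 adjusted over the list alone; median 3.29) and of the ileum (7 of 11 rose, 0 fell; 7 and 1; median 3.33) both passed (adjusted p = 0.00495 and 0.00191), with the ileal marker Clec2h at 5.84. Both had adjusted p = 0.36 with an estimated correlation. After background subtraction in limma-voom the brush border list had a median of 4.23 (median SE 2.08, against 1.09 before) and the lipid absorption list 2.48, and both passed (camera adjusted p = 0.00056 and 0.00037; over 25 alternatives 2.83e-20 to 0.361 and 7.48e-21 to 0.799). Of their genes, 0 of 24 and 5 of 21 were called. The PPAR-alpha, ileum and duodenum lists did not pass there, with medians of 1.76, 2.84 and 1.91. With the background covariate the brush border list passed downward (median −0.46, camera adjusted p = 0.023). Once expected background was taken off both, brush border genes held 0.12%, 0.231%, 0.0678% and 0.0553% of nuclear protein-coding counts in Hypoxia 1 to 4 and 2.47%, 0.252%, 0.226% and 1.83% in Hypoxia+Nitrate 1 to 4 (exact permutation test, p = 0.0571). Hypoxia+Nitrate 1 and 4, the libraries with the largest mitochondrial share, held the highest values of Fabp2 (10010 and 16960 CPM, against 553 and 262 in Hypoxia+Nitrate 2 and 3), and likewise of Rbp2 and Anpep. The TMM factors were 0.220, 1.65, 2.13 and 0.393 in Hypoxia+Nitrate 1 to 4. A lower factor gives a higher CPM, so the size of this gap depends on the scaling.

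**Figure D2:**
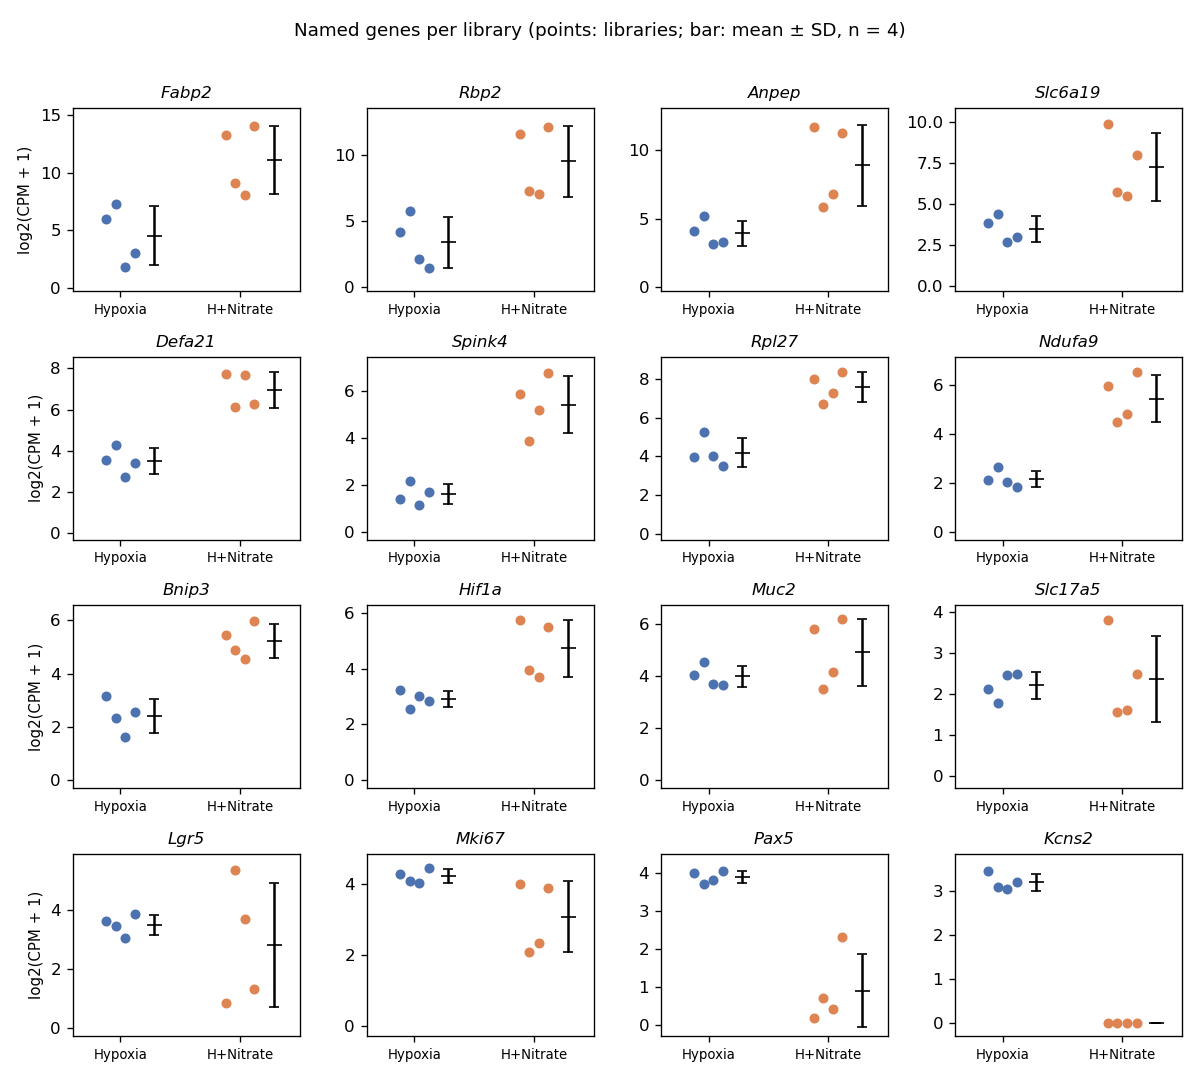
Points are log2(CPM + 1) per library for 16 genes and the bar beside them gives mean ± SD (n = 4 per group). Fabp2, Rbp2, Anpep and Rpl27 lie higher in every Hypoxia+Nitrate library than in any Hypoxia library, values of Slc17a5, Muc2 and Lgr5 overlap between groups, and Kcns2 is at 0 in each Hypoxia+Nitrate library.

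Ribosomal and respiratory gene lists also passed upward. All 30 cytosolic ribosomal protein genes rose, with a median of 3.71 (30 adjusted over the list alone, camera adjusted p = 8.27e-24, or adjusted p = 0.36 with an estimated correlation), among them Rpl27 by 3.46 (SE 0.655). Of 30 nuclear-encoded subunits of oxidative phosphorylation 29 rose and 0 fell (30 adjusted over the list alone, median 3.83, adjusted p = 4.79e-21, or adjusted p = 0.36 with an estimated correlation), Ndufa9 of complex I by 3.79 (SE 0.583). Of 13 mitochondrially encoded genes 3 rose and 10 did not pass (3 adjusted over the list alone), with a median of 7.12 (adjusted p = 1.18e-07, or adjusted p = 0.36 with an estimated correlation). After background subtraction 29 of 30 ribosomal protein genes (median 2.62, SE 0.673) and 8 of 30 oxidative phosphorylation genes (median 2.68) were called higher, and the fit excludes mitochondrially encoded genes. The share of the ribosomal DNA locus was 50.4% ± 32.1 (SD, n = 4) in Hypoxia and 8.16% ± 9.26 (SD, n = 4) in Hypoxia+Nitrate, which did not pass (exact permutation test, 2-sided p = 0.0571).

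Stress and metabolic lists also passed upward, 7 in all. Of 20 NRF2 antioxidant genes 19 rose (19 adjusted over the list alone, median 3.63, adjusted p = 5.20e-10, or adjusted p = 0.36 with an estimated correlation), with Sod1 at 4.52 and Gstm1 at 3.77. Of 26 hypoxia-inducible genes 11 rose and 15 did not pass (11 adjusted over the list alone, median 1.33, adjusted p = 1.69e-05, or adjusted p = 0.36 with an estimated correlation). Higd1a, Bnip3 and Ddit4 rose by 2.80 (SE 0.497), 3.05 (SE 0.544) and 2.52 (SE 0.529). Glycolysis genes rose for 10 of 16 (10 adjusted over the list alone, median 3.57, adjusted p = 1.45e-06, or adjusted p = 0.36 with an estimated correlation), Gpi1 by 4.38. Unfolded protein response genes rose for 13 of 20 (15 adjusted over the list alone, median 2.0, adjusted p = 1.21e-06; Atf4 3.94, Calr 3.33). Heat shock genes rose for 8 of 13 (8, median 2.11, adjusted p = 0.000107; Hspa8 3.32), and p53 targets for 9 of 18 (10, median 1.79, adjusted p = 1.69e-05; Cdkn1a 4.88, Bax 2.41). These 3 lists had adjusted p = 0.36 with an estimated correlation. Iron genes rose for 7 of 14 and fell for 2 (8 and 3 adjusted over the list alone, median 1.44, adjusted p = 0.0137, or adjusted p = 0.36 with an estimated correlation; Fth1 3.11). After background subtraction the hypoxia-inducible median was 1.65 (median SE 1.18, against 0.619 before) with 0 of 22 genes called, and that list and the heat shock list (median 1.24) did not pass. The NRF2 list passed there with a median of 2.52 and 3 of 20 genes called. With library size alone the medians were smaller: 0.096 for hypoxia-inducible, 0.32 for iron, 0.65 for heat shock and 0.69 for unfolded protein response genes. In that scaling p53 targets were at 0.87, NRF2 genes at 1.70, glycolysis genes at 2.37 and all genes at −1.07.

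Genes that handle nitrate and nitric oxide rose for 6 of 19 and fell for 1 (6 and 2 adjusted over the list alone, median 0.87, camera adjusted p = 0.00407; adjusted p = 0.36 with an estimated correlation). The median was −0.06 when only library size was scaled. After background subtraction the list did not pass (median 0.57, 0 genes higher and 2 lower). The arginine enzymes Asl and Arg2 rose by 2.06 (SE 0.445) and 5.75 (SE 1.27) before subtraction. After subtraction neither enzyme passed, with larger standard errors and log2 fold changes of 2.90 (SE 1.26) and 4.83 (SE 2.25). Slc17a5, which encodes the nitrate transporter sialin, was at 3.71 ± 1.05 CPM in Hypoxia and 5.41 ± 5.21 in Hypoxia+Nitrate (mean ± SD, n = 4 per group) and did not pass (log2 fold change 0.54, SE 0.687, edgeR adjusted p = 0.564). Its Hypoxia counts were 0.995 times the expected background, so expression in Hypoxia was not detectable above background at this depth; with library size only the log2 fold change of Slc17a5 was −1.25. Hif1a and Epas1, the oxygen-regulated transcription factors, rose by 2.22 (SE 0.550, adjusted p = 0.0171) and 1.42 (SE 0.434, adjusted p = 0.0367); neither passed after background subtraction, with log2 fold changes of 3.41 (SE 1.18) and 0.33 (SE 0.452). With each of the 3 other scalings the log2 fold change of Epas1 did not pass (1.15 with RLE size factors and 0.99 with library size only), nor did the log2 fold change of Hif1a with library size only (0.75). Neither gene passed when any 1 Hypoxia library was left out, nor Epas1 without Hypoxia+Nitrate 4. Hypoxia counts were 1.16 times the expected background for Hif1a, 4.75 times for Epas1 and 1.29 times for Vegfa. The fold changes of Hif1a and Vegfa therefore start near background. Vegfa, an angiogenic growth factor, did not pass (0.70, SE 0.663, adjusted p = 0.432; log2 fold change of Vegfa −0.97 with library size only).

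Of 24 tight and adherens junction genes 15 rose and 1 fell (17 and 1 adjusted over the list alone, median 2.75, camera adjusted p = 3.68e-06, or adjusted p = 0.41 with an estimated correlation). Tjp1, a junction scaffold, rose by 2.50 (SE 0.652, adjusted p = 0.0209), Epcam by 4.67 (SE 1.03) and Cldn3 by 4.40 (SE 0.924). Ocln (1.32, adjusted p = 0.0569) and Cldn1 (−1.65, adjusted p = 0.245) did not pass, and after background subtraction the list did not pass (median 1.53), with 0 of 23 members called. Goblet cell and mucus genes rose for 7 of 15 (9 adjusted over the list alone, median 1.54, adjusted p = 7.16e-06, or adjusted p = 0.36 with an estimated correlation), with Spink4 at 4.60 (SE 0.7) and Zg16 at 4.76 (SE 1.22). Muc2, the main secreted mucin, did not pass (1.33, SE 0.613, adjusted p = 0.128).

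Paneth cell genes rose for 12 of 16 (14 adjusted over the list alone, median 3.20, camera adjusted p = 7.94e-10, or adjusted p = 0.36 with an estimated correlation). The defensin Defa21 rose by 3.65 (SE 0.635) and Ang4, an antimicrobial ribonuclease, by 2.68 (SE 0.492). The Paneth cell list also passed upward after background subtraction (median 2.28, camera adjusted p = 0.0042) and with the background covariate (median 2.68, 4e-07). Defensins are near-identical copies, so counts within the family may be shared. The list of microbe-induced defence genes did not pass (5 of 21 rose, 2 fell; 6 and 3 adjusted over the list alone; median 0.79, adjusted p = 0.218). Pigr and Reg3a rose by 3.28 and 4.81 and Duox2 fell by 3.77 on the log2 scale. Reg3a held 89.1, 3.18, 1.03 and 39.0 CPM in Hypoxia+Nitrate 1 to 4, which overlapped its Hypoxia values. Hypoxia counts of Pigr, Reg3a and Duox2 were 3.32, 1.34 and 1.49 times the expected background. Among crypt genes, 0 of 17 stem cell genes rose and 1, Ephb2, fell by 1.78 (0 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.346). Lgr5 did not pass (0.36, SE 0.943, adjusted p = 0.789). Of 30 cell cycle genes 4 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.53, adjusted p = 0.00989, or adjusted p = 0.41 with an estimated correlation), with Birc5 at 2.45, Pcna at 3.03 and Cdc6 at −1.87. The cell cycle list did not pass after background subtraction (median 0.057, camera adjusted p = 0.87) or with nuclear protein-coding genes only (0.32). The proliferation marker Mki67 did not pass (−0.99, SE 0.534, adjusted p = 0.184). The stem cell median was −0.05 with upper-quartile factors, and the cell cycle median −0.66 and defence median −0.51 with library size alone.

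Markers of other cell types went both ways. Smooth muscle genes rose for 10 of 14 (11 adjusted over the list alone, median 2.13, camera adjusted p = 1.42e-06), with Cnn1 at 2.40. Fibroblast genes rose for 4 of 16 (4 and 1 lower adjusted over the list alone, median 0.61, adjusted p = 0.00407), with Vim at 2.05. Both lists had adjusted p = 0.36 with an estimated correlation, and the fibroblast median was −0.16 with library size alone. Of 10 MHC class II genes 4 rose (6 adjusted over the list alone, median 2.13, adjusted p = 0.00704, or adjusted p = 0.41 with an estimated correlation), Cd74 by 5.18. The list did not pass without Hypoxia+Nitrate 4 (adjusted p = 0.055; 0.000125 to 0.423 over 25 alternatives). After background subtraction none of these lists passed (medians 1.30, 0.14 and 0.89 for smooth muscle, fibroblast and MHC class II) and 0 of their genes were called. With the background covariate the smooth muscle list passed upward (median 2.52, camera adjusted p = 1.3e-09), and the fibroblast and MHC class II lists did not pass.

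Lists of immune cells did not pass, with few members called. B cell genes fell for 2 of 15, Pax5 (−3.43) and Fcmr (−3.50), and rose for 0 (0 and 2 adjusted over the list alone, median −1.32, camera adjusted p = 0.146). The B cell list passed downward after background subtraction (median −4.78, adjusted p = 0.0067), with the background covariate (0.011), with protein-coding genes only (0.030), without Hypoxia+Nitrate 4 (0.0040) and without Hypoxia+Nitrate 1 and 4 (0.0092), in a range of 0.00403 to 0.659 over 25 alternatives. After subtraction 9 B cell genes were tested, and a gene near 0 in Hypoxia+Nitrate passed the filter there only through residual Hypoxia counts. The downward call in that fit is therefore no separate evidence of a fall. Plasma cell genes rose for 3 of 12, Igha (3.90) and Jchain (2.94) among them (3 adjusted over the list alone, median 0.95, adjusted p = 0.148; median −0.66 with library size alone). T cell genes rose for 2 of 19, Ccl5 (3.84) among them, and fell for 1 (1 and 0 adjusted over the list alone, median −0.38, adjusted p = 0.396). Macrophage genes rose for 2 of 16, C1qa (2.76) among them (2 adjusted over the list alone, median −0.61, adjusted p = 0.740). Neutrophil genes fell for 2 of 10, Ly6g among them (2 adjusted over the list alone, median −0.91, adjusted p = 0.324). Mast cell genes fell for 1 of 9, Mcpt4 (1 adjusted over the list alone, median −2.03, adjusted p = 0.0886). The fry test, which does not compare a list with other genes, called neutrophil and mast cell genes downward (adjusted p = 0.018 and 0.019), and mast cell genes passed downward with protein-coding genes only. Inflammatory cytokine genes rose for 2 of 23, Nfkbia (2.36) and Ccl2 (1.91), and fell for 2 (2 and 2 adjusted over the list alone, median −0.68, adjusted p = 0.930). Interferon genes rose for 1 of 30, Oasl1 (2.42), yet the list passed upward (1 adjusted over the list alone, median 0.30, adjusted p = 0.0428, or adjusted p = 0.36 with an estimated correlation). Its median was −0.10 with upper-quartile factors and −0.39 with library size alone. That call ended with each of the 3 other scalings, DESeq2, a filter of CPM 1 and without Hypoxia 1 (adjusted p = 0.052) or Hypoxia+Nitrate 4 (0.069), in a range of 0.0005 to 0.923 over 25 alternatives.

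Endothelial genes rose for 0 and fell for 3 of 16, Kdr (−3.04) among them (2 lower adjusted over the list alone, median −0.41, camera adjusted p = 0.919). Enteroendocrine genes rose for 2 of 17, Gip (3.62) among them (1 adjusted over the list alone, median 1.29, adjusted p = 0.218; median −0.40 with library size alone). Tuft cell genes rose for 1 of 13, Cd24a (2.10), and fell for 1 (1 and 1 adjusted over the list alone, median −0.59, adjusted p = 0.728). Enteric neuron and glia genes rose for 1 of 15, and adipose genes for 2 of 11, Cidec (2.91) among them (0 and 2 adjusted over the list alone, medians −0.11 and 0.95, adjusted p = 0.489 and 0.115; adipose median −0.00206 with library size alone). Red blood cell genes rose or fell for 0 of 9 (0 adjusted over the list alone, median −0.70, adjusted p = 0.548). Exocrine pancreas genes rose for 1 and fell for 4 of 17, Cela2a among those that fell (1 and 4 adjusted over the list alone, median −2.33, adjusted p = 0.391). The 1 that rose was Zg16, which is also in the goblet cell list. Colon genes rose for 1 and fell for 3 of 10, Hoxd13 among them (1 and 3, median −0.85, adjusted p = 0.306). The fry test called both lists downward (adjusted p = 0.0032 and 0.0015). The camera test leaned upward while the median was below 0 for the cytokine, T cell, macrophage, tuft cell, enteric neuron and red blood cell lists. Hypoxia counts of these 16 immune, interferon and other cell type lists lay at a median of 1.34 to 2.40 times the expected background. Most lists that passed upward lay in that range too, such as the hypoxia-inducible (1.67), nitrate handling (1.73) and junction (1.99) lists. Above it lay immediate early (2.41), duodenum and jejunum (2.48), oxidative phosphorylation (3.18), glycolysis (3.53), smooth muscle (3.95), Paneth cell (6.4) and ribosomal protein (17.2) genes.

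Metabolic and handling lists passed upward. Cholesterol synthesis genes rose for 6 of 22 (7 adjusted over the list alone, median 1.13, camera adjusted p = 0.000563; Hmgcs1 2.84). Xenobiotic genes rose for 10 of 24 (10, median 1.81, adjusted p = 0.000246; Ces2c 4.56). Both had adjusted p = 0.41 with an estimated correlation, and the cholesterol median was −0.01 with library size alone. Vitamin A genes rose for 9 of 15 (10 and 2 lower adjusted over the list alone, median 1.87, adjusted p = 0.00235, or adjusted p = 0.36 with an estimated correlation; Adh1 5.50). Circadian clock genes rose for 6 of 17 (7 adjusted over the list alone, median 1.42, adjusted p = 2.11e-05, or adjusted p = 0.36 with an estimated correlation), the output gene Dbp by 2.82 and the repressor Nr1d1 by 3.31. Immediate early genes rose for 13 of 21 (13 and 1 lower adjusted over the list alone, median 2.17, adjusted p = 1.45e-06), Junb by 3.81. Glucocorticoid response genes rose for 9 and fell for 3 of 15 (9 and 3, median 1.82, adjusted p = 0.00191), with the metallothionein Mt1 at 4.46. Both had adjusted p = 0.36 with an estimated correlation. After background subtraction the immediate early list passed (median 1.64), and the cholesterol, xenobiotic, vitamin A, circadian and glucocorticoid lists did not (medians 0.50, 2.34, 1.26, 1.19 and 1.54).

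**Figure D3:**
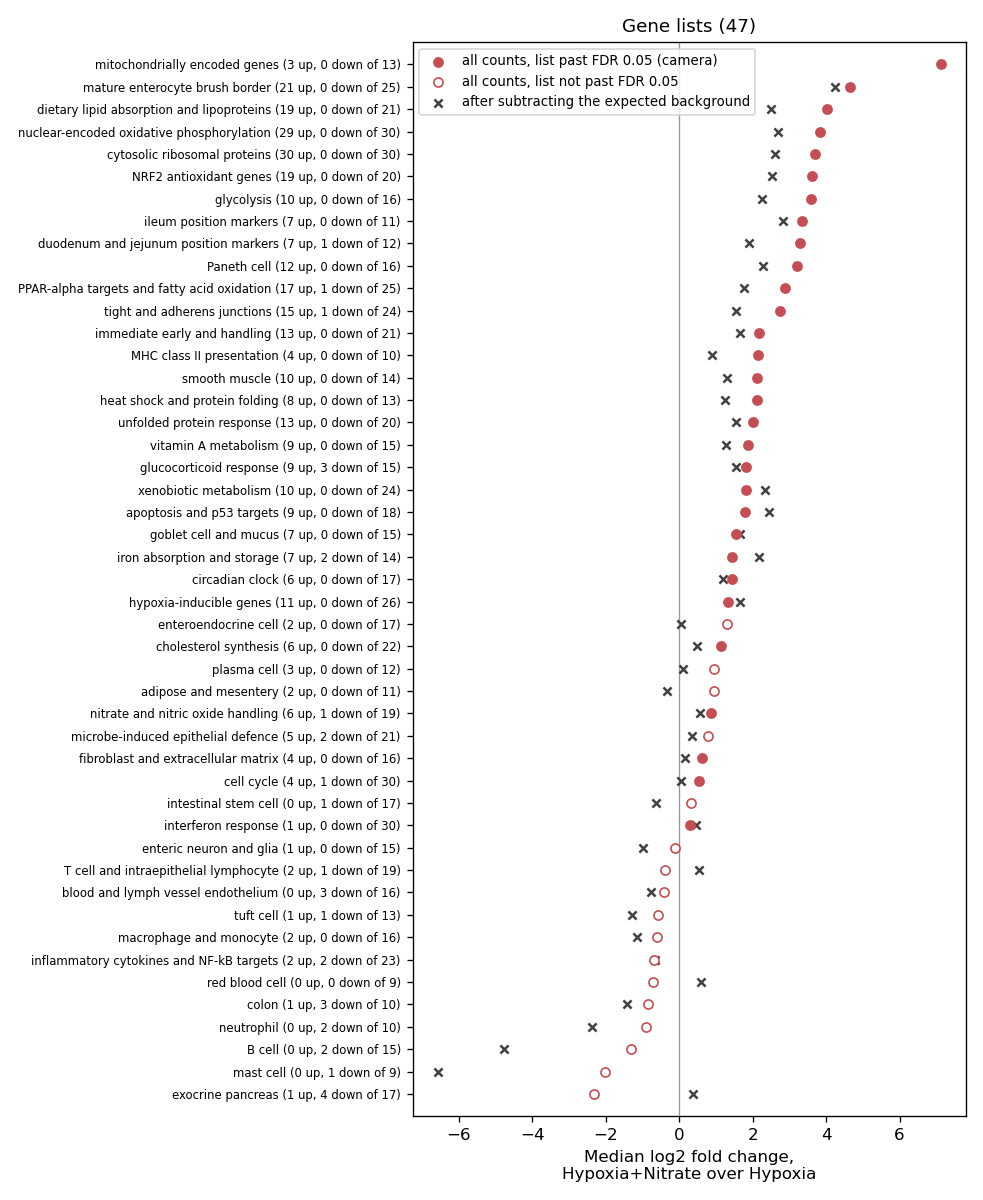
Each row is 1 of 47 gene lists, the x axis gives the median log2 fold change of its members (Hypoxia+Nitrate over Hypoxia), filled circles mark lists past an adjusted p of 0.05 in camera and crosses give the median after background subtraction. Of the 47 lists 30 passed, all upward; 0 passed with an estimated correlation.

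In camera with the preset correlation 30 of 47 lists passed, all upward; with an estimated correlation 0 did, with adjusted p from 0.36. After background subtraction 12 lists passed upward and 1 downward. Without Hypoxia+Nitrate 1 and 4, 23 passed, and the iron, nitrate handling, cell cycle, cholesterol, ileum, xenobiotic, interferon and MHC class II lists did not. In simulated data with even background and no changed list, 12 lists were called. Of the 35 ways to split the 8 samples into 4 and 4, 13 gave 30 or more lists.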

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

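The tests of background subtraction, of library quality, of the X chromosome and of uneven background were chosen only after the results they bear on were seen. The regroupings of samples were planned; the bounds for the share of lower genes near background were set before that share was computed, on a background estimate chosen after the data were seen. A sample stood far from the other 3 of its group in 8 of 220 groups tested, and chance picks out about 1 in 20 groups. Among library measures, Hypoxia+Nitrate 2 held 22.0% of counts at the rDNA locus (others 2.33% to 4.95%) and 3.18% in the 7S RNA genes Rn7s1 and Rn7s2 (others 0.0422% to 0.182%). Among genes, in CPM, the distant samples were Hypoxia+Nitrate 1 for Ang4 (21.3, others 12 to 13.4), Hypoxia+Nitrate 4 for Pax5 (4.00, others 0.142 to 0.625), Hypoxia+Nitrate 2 for Cnn1 (135.1, others 50.7 to 57.7), Hypoxia 3 for Ccl2 (8.38, others 2.47 to 3.42), Hypoxia 4 for Cidec (18.7, others 11.2 to 12.5) and Hypoxia 2 for Slc9a3r1 (55.8, others 3.90 to 8.08).

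Of the 35 splits of the 8 samples into 4 and 4, 1, the real one, gave as many genes as the 8653 called, with or without a minimum of 2-fold. The highest other gave 0. As 1 in 35 is the smallest share possible, this argues against chance for the gene count but cannot exclude it. Every other split also mixes libraries of both groups, which raises the spread within its groups. For the 30 lists the splits do not argue against chance: 13 of the 35 splits gave as many, and the highest other gave 34. A gene count above those of other splits does not say whether nitrate or the make-up of the libraries parts the groups.

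The first pattern is the set of genes lower in Hypoxia+Nitrate. Even background reads in the Hypoxia libraries could account for part of it: 85.02% of 1615 lower protein-coding genes had Hypoxia counts within 2-fold of the expected background, against 45.4% of the higher genes and 73.7% of those not called. These sets leave out the receptor families, mitochondrially encoded genes and genes with less than 300 bp of unique exonic sequence, of 1962 lower protein-coding genes in all. Whether even background at the density of the receptor genes is the whole cause cannot be told apart: 694 (90.2%) of 769 lower genes tested after subtraction were still called lower, but a lower gene could be tested there only where residual Hypoxia counts remained, and the background varied between receptor genes (variance over mean 27.2, 28.9, 48.6 and 34.4 in Hypoxia 1 to 4). Higher transcript levels of these genes in the Hypoxia animals were argued against as the whole cause, as 14.86% lay above 2 times the background. Counts within 2-fold of the background can still hold transcripts: the median was 1.516 times the expected background for lower genes and 1.559 for genes not called. Higher transcript levels therefore stay open for single genes, both the 240 above 2 times the background and those nearer to it. Genomic DNA of male cells is a candidate source of the background that stays open. The X to autosome density ratio over unverified (TEC) loci was 0.4448 (95% bootstrap interval 0.386 to 0.523, from only 6 loci on X). By medians it was 0.543 (0.431 to 0.788). The 9 receptor genes on X gave 0.530, 0.621, 0.672 and 0.825 in Hypoxia 1 to 4, and 6 genes on Y 0.625, 0.478, 0.459 and 0.653. In Hypoxia+Nitrate 1 to 4 the X genes gave 0.428, 0.520, 0.623 and 0.521 and the Y genes 1.81, 0.385, 0.828 and 1.54. The low X ratio was thus not particular to the Hypoxia libraries. Counts at the Y genes in each library go with male mice, but the sex is not given in the sources used here. Transcription from 1 active X might give a like ratio.

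The second pattern is the rise of ribosomal protein and brush border genes. Dilution by background reads at the density of the receptor genes was argued against for ribosomal proteins, since 29 of 30 stayed higher after subtraction. Their share of background-free counts was 0.341% to 2.12% in Hypoxia and 3.23% to 4.39% in Hypoxia+Nitrate (exact permutation p = 0.0286). The 95% interval of the log2 difference, −0.10 to 3.96, included 0. Dilution by a denser background stays open, as no higher level was subtracted. Genes not called held a median of 1.559 times the expected background in Hypoxia. For brush border genes dilution cannot be told apart: the median log2 fold change was 4.66 (median SE 1.09) before and 4.2297 (median SE 2.08) after subtraction, in another test on fewer genes, and the list passed there, but with the background covariate it turned to −0.46. Their share of background-free counts differed by 2.82 on the log2 scale (95% interval 0.0761 to 5.56, exact permutation p = 0.0571), carried by Hypoxia+Nitrate 1 and 4 (2.47% and 1.83%), while Hypoxia+Nitrate 2 and 3 (0.252% and 0.226%) lay near the highest Hypoxia share (0.231%). RNA or library quality that differed between the groups stays open, as 0 Hypoxia+Nitrate libraries reached the lowest background share of a Hypoxia library, so the groups could not be compared at equal quality; so does an effect of nitrate.

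The third pattern is uneven background in the Hypoxia+Nitrate libraries. At a like density, the variance over mean across receptor genes was 5.90 times as large in Hypoxia+Nitrate 2 as in Hypoxia 2, and 399 in Hypoxia+Nitrate 3 against 28.9 in Hypoxia 2, which is consistent with repeated reads of few molecules. Lower background density alone was argued against, as Hypoxia+Nitrate 2 had counts for 16.6 percentage points fewer receptor genes than Hypoxia 2, and Hypoxia+Nitrate 3 had counts for 55.5%. No biological explanation was tested.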

How the results depend on the processing

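The fits restricted to nuclear protein-coding genes, with the background covariate, with background subtracted, without Hypoxia+Nitrate 1 and 4 and without Hypoxia 1 and 2 were chosen only after the data were seen. Unless stated, the cause of a change was not tested. Of the 8653 genes, 7727 were called in the same direction with RLE, 7334 with upper-quartile factors, 8630 with DESeq2 and 1227 after subtraction. The counts of genes past an adjusted p of 0.05, with and without a minimum of 2-fold, were 1800 with library size only, 16708 with no low-count filter (more genes tested), 14689 (14515 at 2-fold) with DESeq2, 15818 (15814) with limma-voom, 20696 with quality weights, 292 with the background covariate, 2000 after subtraction (fewer genes tested) and 4227 without Hypoxia 1 and 2. Without 1 replicate they ran from 1932 to 22454 (22450 at 2-fold), and lists from 29 to 33. With nuclear protein-coding genes only, 26 of 46 lists passed (24 up, 2 down). In that fit the calls ended for iron (camera adjusted p = 0.13), nitrate handling (0.08), cell cycle (0.32), interferon (0.59) and fibroblast (0.1). With the covariate the 4 upward lists were ribosomal proteins, oxidative phosphorylation, Paneth cell and smooth muscle, and 6 lists passed downward. Lists that passed were 0 with an estimated correlation, 11 with fry (7 up, 4 down), 10 with the covariate (4 up, 6 down), 13 after subtraction and 23 without Hypoxia+Nitrate 1 and 4. Without those libraries the calls ended for iron (adjusted p = 0.095), nitrate handling (0.079), cell cycle (0.36), cholesterol (0.10), ileum (0.10), xenobiotic (0.11), interferon (0.079) and MHC class II (0.11). In simulated data with background the covariate fit called 0 of 75 changed genes, so calls lost there say little; it gave 92.0% of those genes the right sign.

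With the replicate block 4791 genes passed, with or without a minimum of 2-fold, and Lgr5 turned to −1.04. Deviations of same-numbered samples correlated at 0.0506, −0.182, 0.184 and −0.0503, and Hypoxia 1 and 3 correlated best with their own number but Hypoxia 2 and 4 with Hypoxia+Nitrate 4 and 2. The labels do not say whether the numbers pair the samples, and correlations this low cannot decide it.

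Directions of single genes turned as follows. The log2 fold change of Slc17a5 was −1.25 with library size only, −0.12 after subtraction, −0.79 without Hypoxia+Nitrate 1 and 4, −1.71 with the covariate and −0.35 to 0.99 without 1 replicate. The log2 fold change of Vegfa was −0.97 with library size only, −1.73 with the covariate and −0.83 without Hypoxia+Nitrate 1 and 4, where the log2 fold change of Muc2 was −0.0736. The log2 fold change of Lgr5 was −1.01 with limma-voom, −2.24 in limma-voom with quality weights, where it passed, and −1.13 to 0.76 without 1 replicate. With the covariate mt-Nd4l was at −0.47, Slc9a3r1 −0.13, Tjp1 −0.0123, Ocln −0.0258, Muc2 −1.13, Arg2 −0.23, Reg3a −0.92, Cd74 −0.0473, Gip −0.18 and Pcna −0.43; of these mt-Nd4l, Slc9a3r1, Tjp1, Arg2, Reg3a, Cd74, Gip and Pcna had been called.

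List directions turned at these adjusted p; the ranges without 1 replicate cover all 8 such fits, whether or not the direction turned. Endothelium: 0.93 with library size only, 0.42 with no filter, 0.80 with limma-voom, 0.77 with quality weights, 0.52 to 0.99 without 1 replicate, 0.92 with the covariate, 0.56 without Hypoxia+Nitrate 1 and 4 and 0.70 without Hypoxia 1 and 2. Inflammatory cytokines: 0.82 with a filter of CPM 1, 0.96 with DESeq2, 0.093 with fry, 0.53 with protein-coding genes only, 0.77 with the covariate, 0.79 after subtraction and 0.34 to 0.92 without 1 replicate. Exocrine pancreas: 0.78 with a filter of CPM 1, 0.64 after subtraction and 0.24 to 0.87 without 1 replicate. Macrophage: 0.25 with fry, 0.69 with protein-coding genes only, 0.33 with the covariate, 0.24 after subtraction, 0.62 without Hypoxia+Nitrate 1 and 4 and 0.30 to 0.99 without 1 replicate. Stem cell: 0.30 with fry, 0.89 with protein-coding genes only, 0.92 with the covariate and 0.77 after subtraction. Tuft cell: 0.093 with fry, 0.75 with protein-coding genes only, 0.92 with the covariate and 0.53 after subtraction. Enteric neuron and glia: 0.59 with fry, 0.89 with protein-coding genes only and 0.53 after subtraction. Red blood cell: 0.19 without contaminant-prone genes, 0.74 with fry, 0.94 with the covariate and 0.98 after subtraction. T cell: 0.59 with fry and 0.46 with the covariate. Plasma cell: 0.89 with protein-coding genes only and 0.24 with the covariate. Enteroendocrine: 0.0059 with the covariate, 0.90 after subtraction and 0.69 without Hypoxia+Nitrate 1 and 4. Neutrophil 0.99 with no filter, and adipose 0.83 after subtraction. With the covariate alone: hypoxia-inducible 0.94, iron 0.80, nitrate handling 0.69, junctions 0.08, goblet cell 0.92, microbe-induced defence 0.041, cell cycle 0.05, brush border 0.023, PPAR-alpha 0.69, cholesterol 0.19, ileum 0.34, xenobiotic 0.041, vitamin A 0.94, interferon 0.92 and MHC class II 0.37.

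Subtraction assumes an even background; the background varied between receptor genes and was not measured at other single genes, so residual counts in Hypoxia, as for Kcns2 (−7.75 after subtraction, counts 1.40 times the expected background), cannot be assigned to background or transcript. Subtraction also changed the test to limma-voom and the genes tested, and these were not varied one by one. Background of 39.1% to 63.7% of nuclear protein-coding counts in the Hypoxia libraries limits what can be seen of genes of low expression there.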

Other observations

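These measures of the libraries were chosen only after the data were seen. Counts between 1 and 40 were multiples of 4 in 33.5% ± 0.776 of genes in Hypoxia+Nitrate and 25.2% ± 0.694 in Hypoxia (mean ± SD, n = 4 per group; exact permutation test, 2-sided p = 0.0286). Across genes, the Spearman correlation of count with exonic length was 0.738 ± 0.0344 in Hypoxia and 0.437 ± 0.0673 in Hypoxia+Nitrate (mean ± SD, n = 4 per group; exact permutation test, 2-sided p = 0.0286). The satellite-like locus Gm10800 took 0.493%, 0.850%, 4.84% and 4.69% of counts in Hypoxia 1 to 4, against 0.00528%, 0.819%, 0.149% and 0.0184% in Hypoxia+Nitrate 1 to 4. No explanation of these values was tested.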
